A study of Mus musculus with 12 samples.

How the data were processed

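Total RNA of cardiac ventricle was measured in 6 wild-type (WT) mice and 6 mice without the alpha2 catalytic subunit of AMP-activated protein kinase (KO), a kinase that senses cellular energy. Per the labels, all animals were 7 months old and of the strain C57B6. Each animal had 1 array with 2 colours. Heart RNA was hybridised against a common reference, a commercial mixture of RNA from 11 mouse cell lines. Per the labels' protocols, 1 µg of total RNA with spike-in controls was amplified and labelled with an Agilent kit, and the dyes were swapped on distinct animals. Heart RNA was in Cy3 for replicates 1 to 3 of each genotype and in Cy5 for replicates 4 to 6, so that dye orientation was balanced over genotype.

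The deposited table held 41174 probes with 1 signed log ratio per probe and array. Background correction, normalization and the filter behind empty cells were not given in the sources used here, and scanner intensities were not used here. The deposited values were read as log2 ratios. Their base is not stated, and natural logarithms could not be excluded from the values. With natural logarithms every difference and standard error would grow by the same factor, and the tests on all features would not change. Settings with a cutoff on the log2 scale, such as the filter on ratio size, would change. Array medians lay between -0.029 and 0.068, so the arrays were already centred. Correlations across probes between arrays of opposite dye orientation were all above 0, so the columns had already been turned to one direction. All 14 measured cardiomyocyte markers were above 0 on every array and all 15 markers of cycling cells were below 0, which sets that direction as heart over reference. No table column was left unused.

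Probes were named through the platform's annotation table. It gave 31700 probes 1 gene symbol, 47 probes several symbols and 9427 probes none. Entrez identifiers of 31564 probes matched the RefSeq annotation of GRCm38.p6, and 0 symbols needed an update. The genome build of the array was not given in the sources used here, so that annotation served only for names, chromosomes and the order of neighbouring genes. A feature was a gene or a probe without 1 symbol. Probes needed at least 2 values in each of the 4 combinations of genotype and dye. This kept 36826 probes and left out 4348, and gave 25821 features, of which 17837 were named genes. For genes with several probes, the planned mean over probes was computed as the array term of an additive fit of probe and array. It equals the plain mean where no value is missing. The plain mean shifts a gene's level where a probe lacks a value, and served as an alternative.

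Differences were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on all 12 arrays, with genotype and dye orientation as terms. P-values were two-sided and adjusted by Benjamini-Hochberg over all features, with 0.05 as the threshold. No pseudocount was needed for log ratios. Errors given with group means are SDs over animals, and errors of differences are the moderated standard errors. The 24 pathway lists and 16 cell type lists, the tests and the rule for named genes were fixed before the data were examined. The rule took the targeted gene and its paralog, the genes that passed in each direction or else the 5 of smallest p, and up to 4 members of smallest p of each list described. Lists were tested with the competitive camera statistic on moderated z values, with a preset correlation of 0.01 between genes, two-sided, adjusted over the 40 lists. Alternatives were camera with an estimated correlation (9 degrees of freedom), camera on ranks, and fry in 1 direction and as a mixed test, for which missing values were filled by fitted ones. Genes around Prkaa2 were compared with all other genes by Fisher's exact test. Python 3.11.15 with pandas 2.3.3 prepared the tables, and matplotlib 3.10.9 drew the plots.

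The pipeline was tested on simulated data with the real levels, dye effects and missing values of the 25821 features, of which 200 were changed. Errors were normal with the moderated SDs of limma, so the simulated data follow the variance model of the test itself. The pipeline recovered 20 of 50 features changed by 0.5, 48 of 50 changed by 1, 50 of 50 changed by 1.5 and 50 of 50 changed by 2 on the log2 scale, with 6 false calls. With fewer changed features the adjustment is stricter, so these shares do not carry over to data with few calls. The list test found the 1 shifted list and called 0 of 39 unshifted ones. Simulated features varied independently of each other, so this does not bear on false calls for lists whose genes vary together. The estimated correlation in the real data was 0.539 for the respiratory chain list and 0.767 for the lung list. The number of arrays limits the precision: the median standard error of a difference was 0.13 on the log2 scale.

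Alternatives were the dye term, the replicate number as a block, array centring, quantile normalization, array weights, variance moderation, the choice of probes, filters on missing values and ratio size, each dye orientation alone, each array left out, and other thresholds. Alternatives chosen after seeing the data were the plain mean of probes, leaving out 3 arrays with markers of other tissues, leaving out 2 arrays with many empty cells, leaving out chromosome 4 from the lists, and the test of all of chromosome 4.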

Results

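The series asked how hearts without AMPK alpha2 differ in gene expression from hearts that have it. Ventricle RNA of 6 WT and 6 KO mice was measured as the log2 ratio to a common reference RNA, so that a value of 0 means equal signal in heart and in the reference cell lines. No 2 arrays were copies of each other, since at most 0.186% of the values of any pair were identical. Most arrays were nearly complete, but 39.2% of probes had no value for WT replicate 3 and 41.7% for KO replicate 4. In WT replicate 3 these lay mainly in the second part of the feature numbers, where 71.6% were empty. In KO replicate 4 they lay in the first part, where 77.5% were empty. KO replicate 1 lacked 26.2% and KO replicate 2 lacked 15.1%. Values on all 12 arrays were present for 6638 probes.

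**Figure D1:**
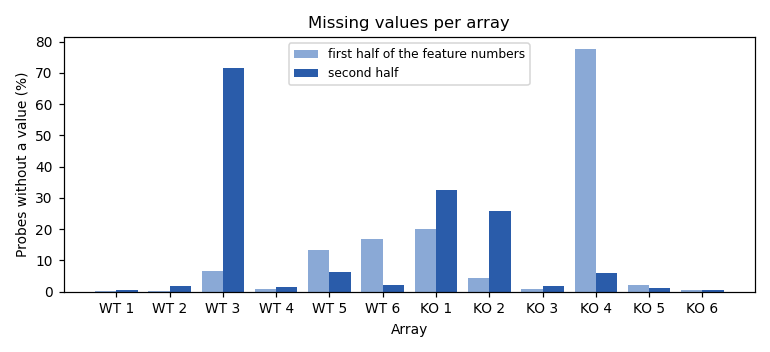
Percent of probes without a value on each of the 12 arrays, for the first and the second part of the feature numbers on the array. WT replicate 3 lacks 71.6% of the second part and KO replicate 4 lacks 77.5% of the first part.

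The RNA had the profile of heart muscle on every array. The 14 measured cardiomyocyte markers were above the reference on all 12 arrays, with a median log2 ratio of 5.39, and the 15 measured markers of dividing cells were below it, with a median of -3.07. Eif2s3y, a gene of the Y chromosome, was above the reference on the 11 arrays that measured it (log2 ratio 2.01 to 3.07). Other measured Y genes, Kdm5d (-0.332 to 0.985), Uty (-0.13 to 0.49) and Usp9y (-0.464 to 0.47), lay on both sides of the reference. Xist, the transcript of the inactive X chromosome, was below the reference on all 12 (-1.92 to -1.24).

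The targeted gene Prkaa2 was measured by 1 probe, and its signal was nearly as high in KO as in WT. The log2 ratio was 4.10 ± 0.09 (SD, n = 6) in WT and 3.89 ± 0.26 (SD, n = 5) in KO, a difference of -0.18 ± 0.10 (SE, limma adjusted p = 0.938). The difference of Prkaa2 was -0.359 ± 0.13 with quantile normalization (limma adjusted p = 0.856), -0.26 without KO replicate 6, -0.125 without KO replicate 3, and -0.057 to -0.359 over all settings. The labels give neither the deleted part of the gene nor the place of the probe, so this value checks nothing about the genotype. Prkaa1, which encodes the alpha1 subunit, differed by -0.06 ± 0.10 (SE, n = 6 and 6, limma adjusted p = 0.973), and its 2 probes differed in sign (-0.22 and 0.045).

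Hyi, a putative hydroxypyruvate isomerase, was the 1 gene that changed between the genotypes, and it rose in KO hearts. Hyi was measured by 1 probe and lies on chromosome 4, 128 measured genes from Prkaa2. Its log2 ratio was -1.95 ± 0.17 (SD, n = 6) in WT and -0.19 ± 0.22 (SD, n = 6) in KO, a 3.38-fold rise. That fold assumes log2 values and would be larger with natural logarithms. The lowest KO animal lay 1.25 above the highest WT animal on the log2 scale, and the rise was 1.75 in the animals with heart RNA in Cy3 and 1.76 in those with heart RNA in Cy5. In limma the difference was 1.76 ± 0.12 (SE), with an adjusted p = 3.92e-05 over 25821 features. With the 3 arrays of each genotype that had heart RNA in Cy5 alone, the adjusted p was 0.451. Over 27 settings it ranged from 6.36e-06 to 0.451.

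With all 12 arrays no gene passed as lower in KO hearts, and the next genes in the order of p did not pass the test. In limma 0 features were lower at adjusted p under 0.05, against 1 with quantile normalization, 1 with heart RNA in Cy3 alone, 1 without the 3 arrays with most markers of other tissues and 2 without KO replicate 6. In simulated data the test recovered 20 of 50 changes of 0.5, so changes of that size can be missed. At unadjusted p under 0.05 there were 1377 features, 644 of them higher and 733 lower in KO, where 1291 are expected by chance. Among features measured on all 12 arrays, the KO and WT animals did not overlap in 0.267%, and chance gives 0.216%.

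Of the genes higher in KO with the smallest p after Hyi, Hdac1, a histone deacetylase, differed by 0.75 ± 0.11 (SE), and Extl1, a glycosyltransferase of the exostosin family, by 0.94 ± 0.15. Arhgef17 differed by 0.53 ± 0.08, and Tmprss13, a membrane serine protease, by 0.88 ± 0.16. On the lower side stood Egf, which encodes epidermal growth factor (-1.18 ± 0.18), Gnb3, a beta subunit of G proteins (-0.999 ± 0.179), Plin3, a lipid droplet protein (-0.75 ± 0.14), Trabd2b (-0.54 ± 0.09) and Tcea3, a transcription elongation factor (-0.52 ± 0.10). The limma adjusted p of these 9 genes was 0.138 to 0.323. With features filtered for a ratio away from 0, Arhgef17 and Hdac1 passed with adjusted p = 0.0493 (n of 5 or 6 animals per genotype, limma). With features measured on all arrays Arhgef17 passed with adjusted p = 0.0287, and with quantile normalization Egf passed with adjusted p = 0.00916 (limma).

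**Figure D2:**
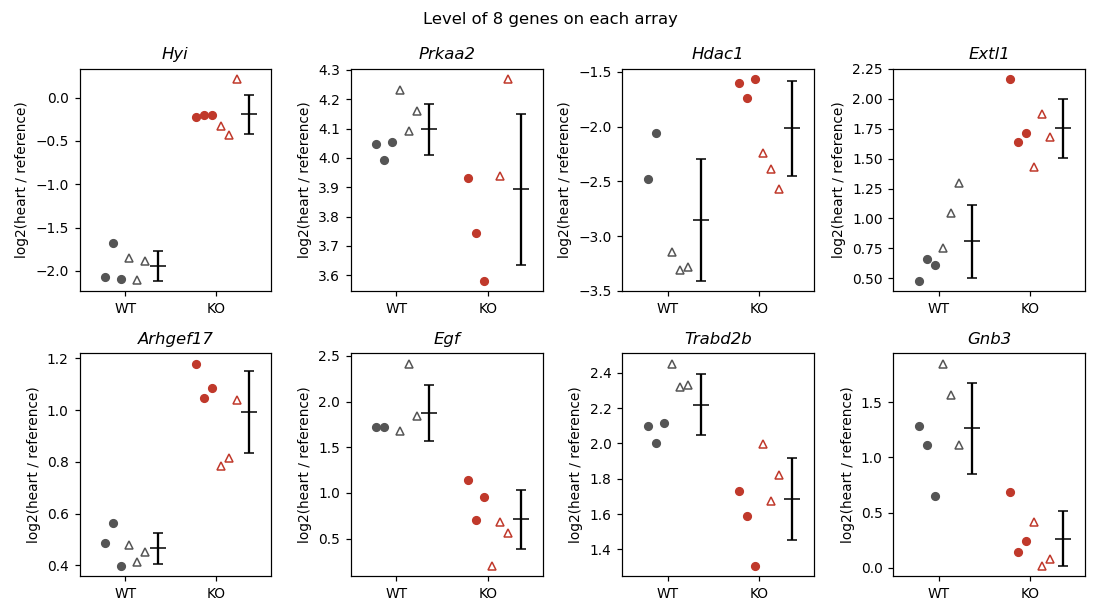
Log2 ratio of heart over reference RNA for 8 genes on each array, WT in grey and KO in red, filled circles for heart RNA in Cy3 and open triangles for Cy5, with the mean and SD of each genotype. Hyi lies at -1.95 in WT and -0.19 in KO with no overlap, while the difference of Prkaa2 is -0.18.

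Genes of the AMPK complex and of its upstream kinases did not shift in 1 direction as a group. Of 11 measured members 3 were above and 8 below the WT level, with a median difference of -0.04. Prkab1, the beta1 subunit, had the smallest p with -0.33 ± 0.11 (SE), and Prkab2, the beta2 subunit, differed by 0.19 ± 0.10. Neither passed the test over all features (limma adjusted p = 0.899 and 0.935), and 0 members passed when adjusted over the list alone. The list's adjusted p was 0.438 in the camera test and 0.045 in the mixed test of fry, which counts members that differ in either direction. Values filled for fry can make the latter p too small.

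Transcripts of the respiratory chain and ATP synthase lay slightly lower in KO hearts, to an extent that depended on single arrays. Of 74 measured members 63 were below the WT level and 11 above, with a median difference of -0.10 on the log2 scale. Ndufb9 (-0.25 ± 0.13, SE, and -0.16 without WT replicate 1), Ndufs7 (-0.21 ± 0.12, and -0.121 without WT replicate 5) and Ndufa5 (-0.18 ± 0.11, and -0.101 without WT replicate 5) of complex I were among the members of smallest p, and Ndufs5 of the same complex went the other way (0.18 ± 0.11), though its 2 probes differed in sign (-0.137 and 0.438) and the gene lies on chromosome 4. None of the 74 passed over all features or when adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 0.00376), but adjusted p = 0.916 with an estimated correlation and 0.847 with fry. The adjusted p was 0.237 with array weights, 0.265 without the 2 arrays with most empty cells, 0.62 (median -0.023) without WT replicate 5, 0.299 (-0.045) without KO replicate 1 and 0.0789 (-0.049) without WT replicate 1, and the median was -0.064 without KO replicate 4, while the list was lower by -0.187 (1.05e-10) with quantile normalization and by -0.141 (2.48e-07) without WT replicate 6.

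Other energy pathways did not pass camera. Fatty acid uptake and beta-oxidation had a median of -0.08, with 15 of 23 members below the WT level. Glucose uptake and glycolysis had -0.06 (13 of 21 below), and the tricarboxylic acid cycle had -0.06 (13 of 17 below). Targets of PPAR, a receptor for fatty acids, had 0.08 (8 of 13 above). Mitochondrial biogenesis and dynamics (22 genes) had 0.015, cardiolipin and phospholipid synthesis (23) -0.015, and synthesis of fatty acids, triglycerides and cholesterol (23) 0.036. Their camera adjusted p ranged from 0.187 to 0.757. Cpt1a, which admits fatty acids to mitochondria, differed by 0.27 ± 0.11 (SE), Angptl4, an inhibitor of lipoprotein lipase, by 0.97 ± 0.40 (0.636 ± 0.381 without KO replicate 6), Pdhb of pyruvate dehydrogenase by -0.32 ± 0.10 and Lipe, the hormone-sensitive lipase, by 0.42 ± 0.13. None of these passed (limma adjusted p = 0.828 to 0.911).

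Members of 7 lists passed when adjusted over the list alone, and 0 of the 667 distinct list members passed over all features, while 38 of these 667 had an unadjusted p under 0.05. Over all features 1377 of 25821 had such a p, a similar share. Slc2a1, the glucose transporter GLUT1, differed by -0.41 ± 0.10 (SE), with limma adjusted p = 0.0418 when adjusted over the list alone for glycolysis and 0.0398 for hypoxia and angiogenesis. Pgm1, which links glucose phosphates to glycogen, differed by -0.66 ± 0.15 (limma adjusted p = 0.0129 when adjusted over the list alone for glycogen metabolism). Both lie on chromosome 4. Uchl1, a ubiquitin hydrolase, differed by 0.59 ± 0.16 and passed over the fetal programme alone and over the Schwann cell and neuron list alone (limma adjusted p = 0.0396 and 0.0223). The other 3 belonged to skeletal muscle and thymus markers. The glycogen list as a whole had a median of -0.001 (15 genes, camera adjusted p = 0.354), and the hypoxia list 0 (20 genes, 0.778). In the mixed test of fry 6 lists passed, with adjusted p = 0.000148 for hypoxia and angiogenesis, 0.0124 for thymus markers, and 0.045 each for AMPK and its kinases, mitochondrial biogenesis and dynamics, autophagy and lysosome, and skeletal muscle markers. Missing values had been filled by fitted ones, which add no residual spread, so these p-values can be too small. The mixed test was not run on other splits of the arrays.

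Genes of calcium handling and ion channels lay slightly higher in KO hearts, again to an extent that depended on single arrays. Of 28 measured members 23 were above the WT level and 5 below, with a median difference of 0.10. The pacemaker channel gene Hcn4 (0.31 ± 0.11, SE) and the potassium channel genes Kcnq1 (0.26 ± 0.12, and 0.164 without WT replicate 4) and Kcnj2 (0.35 ± 0.18, and 0.213 without KO replicate 6) had the smallest p, with Slc8a1, the sodium-calcium exchanger (0.23 ± 0.12, and 0.14 without KO replicate 3), 1 of whose 8 probes went the other way. None passed over all features or when adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 0.0167), but adjusted p = 0.908 with an estimated correlation and 0.617 with fry. The adjusted p was 9.85e-05 (median 0.23) with heart RNA in Cy3 alone but 0.996 (0.01) in Cy5 alone, 0.525 without the 3 arrays with most markers of other tissues (WT replicate 2, KO replicate 1 and KO replicate 6), 0.547 (median 0.003) with quantile normalization, 0.417 (0.028) without KO replicate 1 and 0.0789 (0.044) without WT replicate 1.

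Structural, stress and signalling lists did not pass camera. The adult sarcomere (18 genes, median -0.018), the fetal and hypertrophic programme (16, 0.019) and extracellular matrix and fibrosis (30, -0.022) lay near 0, with camera adjusted p of 0.757, 0.874 and 0.187. Autophagy and lysosome genes had a median of -0.07 (16 of 25 below, adjusted p = 0.0604), with Ctsl, a lysosomal protease, at -0.53 ± 0.16 (SE) and Map1lc3b, an autophagosome protein, at -0.25 ± 0.08. Inflammation and complement had 0.14 (13 of 18 above, adjusted p = 0.12), with Serpina3n at 0.53 ± 0.20, or 0.319 ± 0.165 without KO replicate 6, its highest array (2.09, other KO arrays at most 1.16), and immediate early genes had -0.08 (15 of 22 below, 0.156). The mTOR and insulin list (22 genes, -0.012), FOXO and atrophy genes (12, -0.011), heat shock and unfolded protein response (21, 0.037), antioxidant defence (23, 0.035), the circadian clock (18, -0.005) and interferon response (22, -0.022) had camera adjusted p from 0.438 to 0.979. Mean and median differed in sign for antioxidant defence, whose mean was -0.016, and for the clock, whose mean was 0.008.

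**Figure D3:**
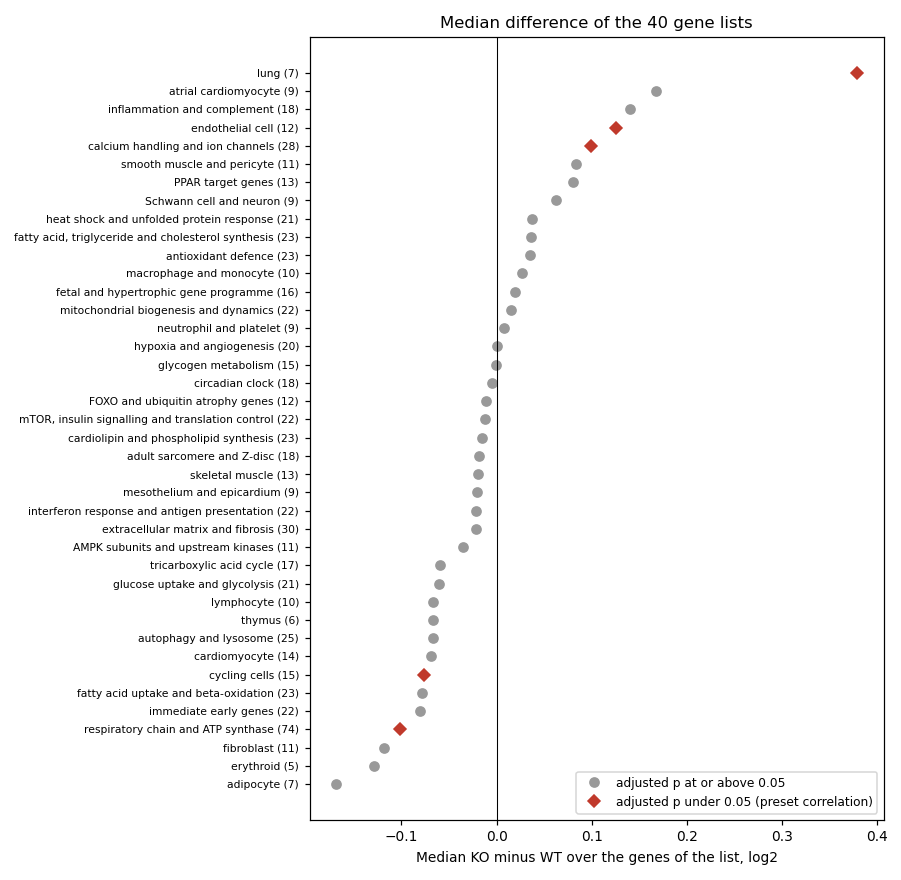
Median KO minus WT difference of each of the 40 gene lists on the log2 scale, with the number of measured genes in brackets. Diamonds mark the 5 lists past an adjusted p of 0.05 with a preset correlation, from the respiratory chain at -0.10 to the lung markers at 0.38, and 0 of them pass with an estimated correlation.

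Markers of endothelial cells lay slightly higher in KO hearts. Of 12 measured markers 8 were above the WT level (median 0.12), among them Esam (0.34 ± 0.12, SE), Cdh5 (0.37 ± 0.14) and Tek, the angiopoietin receptor (0.29 ± 0.11), which lies on chromosome 4, 46 genes from Prkaa2. No member passed when adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 0.0234), but adjusted p = 0.908 with an estimated correlation, 0.864 (median 0.044) with heart RNA in Cy5 alone against 0.00126 (0.239) in Cy3 alone, and 0.517 (0.038) with quantile normalization. Without the 3 arrays with most markers of other tissues its camera adjusted p was 0.195 (0.078). The list also did not pass, at medians close to that with all arrays, without the genes of chromosome 4 (0.118, adjusted p = 0.0609), WT replicate 1 (0.125, 0.134), KO replicate 1 (0.109, 0.135) or KO replicate 6 (0.103, 0.0563), and it passed with larger medians without WT replicate 4 (0.206, 0.00887) or KO replicate 4 (0.203, 0.0058).

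Markers of dividing cells lay slightly lower in KO hearts, and the difference from the endothelial list was not tested. Of 15 measured markers 12 were below the WT level (median -0.08), among them the kinase gene Aurkb (-0.60 ± 0.17, SE) and Rrm2 of nucleotide synthesis (-0.32 ± 0.15). No member passed when adjusted over the list alone. The list passed camera with a preset correlation (adjusted p = 0.0423), but adjusted p = 0.908 with an estimated correlation, 0.814 (median 0.056) with heart RNA in Cy5 alone against 9.85e-05 (-0.311) in Cy3 alone, 0.636 (-0.015) with quantile normalization and 0.0589 (-0.129) with the replicate block. Without the 3 arrays with most markers of other tissues its camera adjusted p was 0.485 (-0.038). The list did not pass at smaller medians without KO replicate 1 (-0.041, adjusted p = 0.533), WT replicate 1 (-0.049, 0.276) or WT replicate 2 (-0.053, 0.0525), nor at larger ones without WT replicate 4 (-0.161, 0.0528), KO replicate 3 (-0.127, 0.0767) or KO replicate 6 (-0.089, 0.0503), and it passed at -0.119 to -0.123 without WT replicates 5 and 6 or KO replicates 4 and 5.

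The remaining marker lists had camera adjusted p from 0.156 to 0.979. Medians were -0.07 for cardiomyocytes (14 genes), -0.12 for fibroblasts (11), 0.08 for smooth muscle and pericytes (11), 0.027 for macrophages and monocytes (10), -0.07 for lymphocytes (10), 0.008 for neutrophils and platelets (9) and -0.13 for erythroid cells (5). They were -0.17 for adipocytes (7), 0.17 for atrial cardiomyocytes (9), -0.02 for skeletal muscle (13), 0.062 for Schwann cells and neurons (9), -0.021 for mesothelium (9) and -0.07 for thymus (6). Mean and median differed in sign for skeletal muscle, thymus, and neutrophils and platelets, whose means were 0.048, 0.014 and -0.062.

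Several samples carried transcripts of tissues other than ventricle. KO replicate 6 had lung transcripts, with a log2 ratio of 6.13 for Sftpc, the surfactant protein C gene, against at most 2.19 elsewhere. It also had liver transcripts, with 5.90 for albumin (Alb) against at most 0.567 elsewhere, a gene chosen after its values were seen. WT replicate 2 and KO replicate 1 had the atrial light chain Myl7 at 7.19 and 7.09, against 0.883 to 4.96 on the other 8 arrays that measured it. A weaker atrial signal was present on 3 more arrays, with the atrial light chain Myl4 at 3.67 in WT replicate 6, 2.16 in KO replicate 6 and 1.90 in KO replicate 5, against -0.298 to 0.084 on the remaining 7. WT replicate 2 also had the fat markers Adipoq (3.93) and Ucp1 (3.81), the latter a gene of brown fat. The fat markers Lep, Cidea, Fabp4 and Plin4 were at most 0.353 above the median of the other arrays there. Cidea, Fabp4 and Plin4 were far above the reference on all arrays that measured them (lowest 4.07). The lung list was higher in KO as a group (7 of 7 members above, median 0.38, camera adjusted p = 0.0249), but adjusted p = 0.908 with an estimated correlation. Without KO replicate 6 its median was 0.007 and its adjusted p 0.45, while without WT replicate 5, WT replicate 4 and KO replicate 1 the median stayed at 0.387, 0.365 and 0.379, with adjusted p of 0.138, 0.0685 and 0.0526. Without WT replicate 2, KO replicate 1 and KO replicate 6, which keeps WT replicate 6 and KO replicate 5, 1 list passed camera, the respiratory chain (adjusted p = 5.29e-05), and Hyi passed with limma adjusted p = 0.00039, with 1 unnamed probe.

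**Figure D4:**
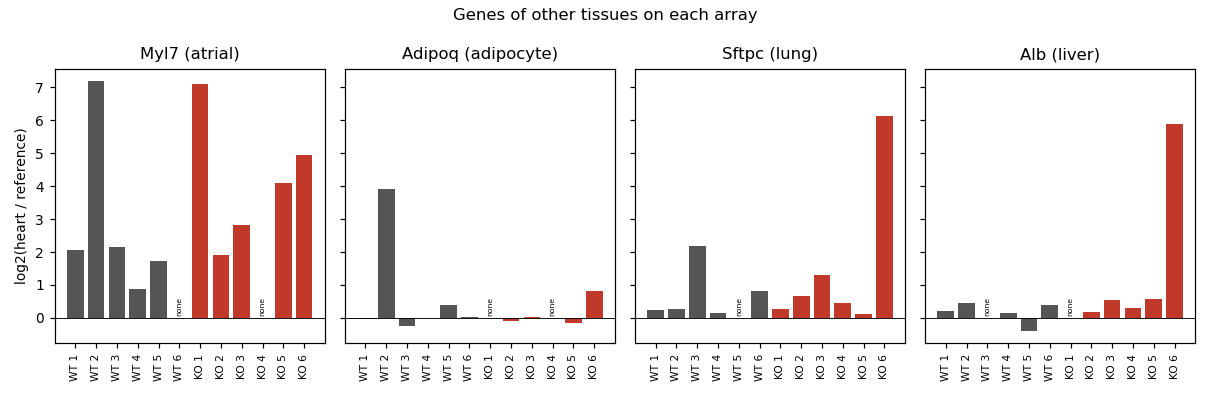
Log2 ratio of heart over reference RNA on each array for 4 genes typical of atrium, fat, lung and liver, WT in grey and KO in red, with arrays that lack a value marked none. Myl7 reaches 7.19 in WT replicate 2 and 7.09 in KO replicate 1, Adipoq 3.93 in WT replicate 2, and Sftpc 6.13 and Alb 5.90 in KO replicate 6.

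Genes that lie near Prkaa2 on chromosome 4 were compared with all others, because a knockout made in stem cells of another strain can keep that strain's DNA beside the targeted gene. None of the 50 measured genes on each side passed in limma at adjusted p under 0.05. At unadjusted p under 0.01, 5 of these 100 genes differed, against 183 of 17702 other genes (odds ratio 5.04, 95% interval 1.58 to 12.4, Fisher's exact test, two-sided p = 0.00418). They were Patj, Pgm1, Jak1 and Tceanc2, lower in KO, and Echdc2, higher in KO, named after their values were seen. With 100 genes on each side it was 8 of 200 (p = 0.00131), and with 20 on each side 2 of 40 (p = 0.0666, both Fisher's exact test).

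The excess extended over a long stretch of the chromosome. Over all of chromosome 4, in a test chosen after seeing the data, 36 of 1038 genes had an unadjusted p under 0.01, against 152 of 16764 elsewhere (odds ratio 3.93, 95% interval 2.64 to 5.71, Fisher's exact test, two-sided p = 2.14e-10). Of these, 17 were higher and 19 lower in KO. The share was 3.46% on chromosome 4 and at most 1.25% on any other chromosome. Of the 20 named genes of smallest p, 9 lay on chromosome 4, including Hyi, the gene of rank 128 from Prkaa2, with Hdac1, Extl1, Trabd2b and Tcea3. In the stretch from 100 genes before Prkaa2 to 399 genes after it, 31 of 500 genes had a p under 0.01, against 5 of 539 on the rest of the chromosome. The bounds of that stretch were also chosen after seeing the data.

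**Figure D5:**
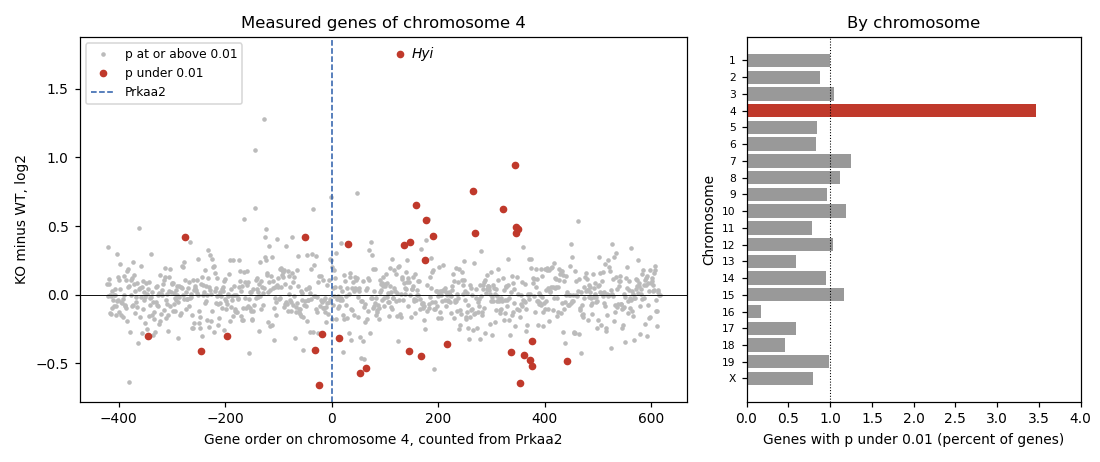
Left, KO minus WT log2 difference of the measured genes of chromosome 4 in annotation order counted from Prkaa2, with genes of unadjusted p under 0.01 in red. Right, the percent of genes with p under 0.01 on each chromosome, with a dotted line at 1 percent, which is 3.46 for chromosome 4 and at most 1.25 elsewhere.

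The dye orientation left its own mark on the ratios. In limma 1474 features, 5.71% of those tested, differed between the orientations at adjusted p under 0.05. The interaction of dye and genotype passed in limma for 0 features, but for 52 without KO replicate 5 and 6 without KO replicate 3. With all arrays 1241 features had an interaction at unadjusted p under 0.05, where 1291 are expected by chance. Medians of 4 lists lay far apart between heart RNA in Cy3 and in Cy5, at -0.311 and 0.056 for cycling cells, 0.23 and 0.01 for calcium handling, 0.239 and 0.044 for endothelial cells and 0.129 and 0.648 for lung, and the interaction was not tested for lists.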

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

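Tests of the atrial genes, of genotype and noise for the other-tissue markers, and of explanations for chromosome 4 were chosen after the results were seen. The counts of splits for changed genes and lists, the tests of further lung genes and of hepatocyte genes and the comparison of the 100 genes nearest Prkaa2 were set before their results.

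KO replicate 6 held lung and liver transcripts, and within the KO group its dye-adjusted values stood far from the others for Sftpd (3.34, others -0.11 to 0.66), Scgb1a1 (4.32, others -0.46 to 0.83) and the mean of the lung list (2.11 above the list's mean over all arrays, others -0.53 to 0.19). RNA of lung is a candidate explanation: 10 measured lung genes that are not on the lung list, listed without looking at their values, exceeded the median of the other 11 arrays by a median of 1.15, and 8 of them were above every other array. RNA of liver may be present too: 16 measured hepatocyte genes, listed without looking at their values, exceeded the median of the other arrays by a median of 2.46, and 15 of them were above every other array, while kidney, pancreas and brain genes had medians of -0.05, 0.21 and -0.03. The tables argue against a genotype difference, since the other 5 KO arrays differed from WT by a mean of 0.01 over the lung genes. Thymus, lymphocyte, neutrophil and platelet markers had a mean excess of -0.07, which argues against a general rise of other-tissue markers on that array. Noise in both directions would leave such a mean near 0, so this value cannot show it. How RNA of lung or liver would have entered the sample stays open.

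Atrial markers were highest in WT replicate 2 and KO replicate 1, and weaker in WT replicate 6 (Myl4 3.67, Sln 2.85), KO replicate 6 (Myl4 2.16) and KO replicate 5 (Myl4 1.90). Atrial tissue in the ventricle sample is a candidate explanation: beside Myl7 and Myl4, 4 of the 7 other atrial genes (Sln, Dkk3, Kcnj3 and Pam) had a mean in these first 2 arrays over 0.5 above the median of the other 10, although Pam (1.86 and 2.20) was at 1.66 in WT replicate 3. Bmp10, Nr2f2 and Nppa did not, and Nppa is high in ventricle on all arrays. A genotype difference is argued against as the whole cause, since without these 2 arrays KO differed from WT by 0.21 over the 9 atrial genes (95% interval over animals -0.493 to 0.903, below the 1.046 that is 0.5 of the excess), but a smaller one stays open, with Myl7 at 1.92 to 4.96 in 4 KO animals and 0.883 to 2.17 in 4 WT animals. WT replicate 2 also stood apart in the mean of the adipocyte list (1.27, others -0.47 to 0.09), with Adipoq, Cidec and Ucp1 as its high members. Its other measured members lay close to the median of the other arrays (Lep -0.048, Cidea -0.177, Fabp4 0.051 and Plin4 0.353 from it). Cidea, Fabp4 and Plin4 were high on all arrays that measured them (lowest 4.07), so a small addition of fat RNA may not show in them.

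The other single-array departures were spread over the groups. They were Egf in WT replicate 5 (2.43, others 1.68 to 1.85), Tcap in WT replicate 3 (6.85, others 5.23 to 5.66), Timp2 in KO replicate 1 (-1.36, others -1.16 to -1.06), Cry2 in KO replicate 3 (0.21, others 0.53 to 0.67) and Serpina3n in KO replicate 6 (1.95, others 1.03 to 1.21), the array with liver and lung transcripts. Ccna2 stood apart in WT replicate 6 (-4.48, others -4.12 to -3.93) and in KO replicate 1 (-4.73, others -4.31 to -4.07). In all 11 of 182 groups of values stood out by the gap to the nearest value, and chance gives about 5%.

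Genes of chromosome 4 differed between the genotypes more often than genes elsewhere, in both directions. Of 100 dye-balanced splits of the 12 arrays 1 gave as many such genes, the real one with 36, and the highest other gave 23, which argues against chance for the count. Chromosome 4 was picked after seeing the data, and the splits were not searched for their own highest chromosome, so chance is not excluded. An effect of AMPK alpha2 loss that ignores where genes lie would give no excess near Prkaa2. The odds ratio for the 100 genes nearest Prkaa2 was 5.04 (95% interval from 1.58). Fisher's exact test counts neighbouring genes as independent, though, and the splits were not run for these 100 genes. Of these genes 0 passed at adjusted p under 0.05. That ratio therefore cannot decide on this effect, which stays open as the whole cause. Weaker hybridization to probes through a variant that KO animals alone carry is argued against for the 17 higher genes by their odds ratio of 3.97. For the 19 lower genes that explanation cannot be told apart from lower expression: in 7 of the 9 with several probes every probe fell by at least 0.5 of the gene's difference, in the other 2 it did not, and 10 have 1 probe. Linked DNA of another strain around Prkaa2 is a candidate explanation, and the odds ratio of 5.04 goes with it, under the same limit. The genes of p under 0.01 did not thin out evenly with distance, though (4 in the 100 before Prkaa2, then 4, 9, 3 and 11 in successive 100s from it on). An effect of AMPK loss on single genes among them, Hyi included, stays open.

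Other splits of the arrays bear on the counts. For the genes changed, 2 of 100 dye-balanced splits gave at least 1 gene, with the real value 1 and the highest other 2. In 98 of the 100 splits no gene passed, which argues against chance for the count without excluding it. The 1 other split with genes gave more than the real one, but it kept 5 of the 6 WT arrays together. It was therefore close to the real split. In limma the smallest unadjusted p was 1.52e-09 in the real split and 1.94e-06 in the split with 2 genes. For the 5 lists, 62 of 100 splits gave at least as many, and the highest other gave 13, so that chance cannot be excluded.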

How the results depend on the processing

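Alternatives for the plain mean of probes, the left-out 2 or 3 arrays and chromosome 4 were chosen after seeing the data. Hyi passed in 26 of 27 settings, with differences of 1.67 to 1.82, and not with heart RNA in Cy5 alone. The cause of the changes below was not tested, apart from fewer arrays or features where a setting names them. Genes changed numbered 2 with quantile normalization (1 lower, Egf), 2 with each probe as a feature (2 higher, with Ppt1), 2 with features on all 12 arrays (2 higher, with Arhgef17), 3 with the filter on ratio size (3 higher, with Arhgef17 and Hdac1), 2 with Cy3 alone (1 lower), 0 with Cy5 alone (0 higher) and 2 without the 3 arrays with other tissues (1 lower). Leaving out each array gave 1 to 3 genes changed and 0 to 2 lower, the 3 and the 2 without KO replicate 6. Lists past the threshold numbered 2 without the dye term, 8 with quantile normalization, 2 with array weights, 3 without moderation, 0 with features on all 12 arrays, 1 at adjusted p under 0.01, 0 with an estimated correlation, 0 with fry in 1 direction, 6 with its mixed test, 3 on ranks and 1 without the 3 arrays. Leaving out each array gave 0 to 12 lists: 0 without KO replicate 1, 12 without WT replicate 2, 9 without WT replicate 6, 3 without WT replicate 5, and 2 without WT replicate 1 or KO replicate 6. Each of the 5 lists passed in 14 to 23 of its settings. Genes beside Prkaa2 past the criterion numbered 5 at unadjusted p under 0.01, 1 over chromosome 4, and 36 over chromosome 4 at unadjusted p under 0.01. The interaction of dye and genotype passed for 0 to 52 features when each array was left out, with 52 without KO replicate 5 and 6 without KO replicate 3. Signs turned for Prkaa1 (0.045) and Tnnt2 (-0.208) on the probe of largest ratio, Acta1 (0.083), Lcn2 (-0.129) and Sftpa1 (-0.129) in Cy3, Hspb6 (-0.061), Ccna2 (0.052) and the cycling list (0.056) in Cy5, Klf15 (-0.058) with the plain mean, and Sftpa1 (-0.091) without the 3 arrays, none of them called genes. Replicate numbers of the genotypes share only a number: correlations of same-numbered deviations were -0.232 to 0.022, and 1 of 6 numbers matched best with its own. With the replicate block 1 gene, Hyi, was called (adjusted p = 0.0011) and 4 lists. Without scanner intensities, signal over background was not analysed here, so low-signal probes could not be set apart.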

Other observations

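Apart from the heart samples' own markers, KO replicate 6 stood out in the breadth of what it added. It had 245 features more than 1 log2 unit above every other array, against 0 to 48 on the other arrays. Among the highest, named after their values were seen, were Ambp (7.19), Fabp1 (6.93) and Fgg (6.61), genes of secreted and lipid-binding liver proteins, which were at most 0.688 elsewhere. Haptoglobin (Hp) was at 4.78 and Cyp2e1, a liver cytochrome, at 5.32, though both reached 2.38 and 3.00 on another array.

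Along chromosome 4, the 100 genes from Pef1 to Zfp46 held 11 genes of unadjusted p under 0.01, and windows of 100 neighbouring genes on any other chromosome held at most 4. This window was found by search over the same data. In it lay Extl1 and Tcea3, which differed in opposite directions.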
